A study of Mus musculus with 4 samples.

How the data were processed

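RNA that came down with an antibody against KIF5C, the heavy chain of a kinesin-1 motor, or with a control mouse IgG was sequenced from the hippocampus of mice aged 7 to 9 weeks. Each co-immunoprecipitation used the hippocampi of 2 mice, and per the series' design text 6 co-immunoprecipitations were pooled into 2 samples, giving 2 libraries for each antibody. The text does not state whether the 6 were counted per antibody, so the number of animals behind a library is not given here. No source used here says that the 2 libraries of an antibody came from separate pools of animals, so p-values measure only the spread between these libraries, which may be technical. There was no library of input RNA among the samples analysed here, so a higher level means higher in the KIF5C precipitate than in the IgG precipitate.

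The deposited table holds whole-number read counts per gene for the 4 libraries, made by the authors and not normalized. Its columns were assigned to libraries through the sample descriptions in the labels. Salmon and DESeq are named in the submitters' processing notes with the genome build GRCm38, without versions or settings. The annotation, the strandedness and the way in which estimated counts became whole numbers are not given in the sources used here. Salmon shares reads between similar transcripts, so genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, snoRNA families and rRNA-like loci, have uncertain counts. Overlapping and antisense genes are uncertain for the same reason.

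A second deposited table holds the authors' own comparison of the antibodies. Its log2 fold changes and their standard errors are on the log2 scale, per the file headers, and run from KIF5C to IgG, so that a negative value means higher in the KIF5C precipitate. Its fold column, a linear ratio made by the authors, runs the other way and is filled for 963 genes. Its p-values and adjusted p-values are the authors' own, as is the test statistic, a score deposited per gene. The mean normalized counts deposited per gene were not used here.

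The count table has 37411 gene rows, of which 36218 (96.8%) matched a symbol of GENCODE mouse release 21 (GRCm38), and another 589 matched through an older symbol in RefSeq. In 27 rows a spreadsheet had turned the gene name into a date. These rows held 0.121% to 0.252% of the counts of a library and stayed in the tests under a number, but they are not named. Coordinates, transcript lengths and GC content come from that GENCODE release, with the longest annotated transcript standing for its gene. Of the 14357 genes tested, 14274 (99.4%) had a GC value.

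Libraries of the 2 antibodies were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the low-count filter filterByExpr (minimum count 10, minimum total 15) and the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A log2 fold change is KIF5C over IgG from this fit, and its standard error (SE) was taken as its size divided by the square root of F. Normalised abundances are TMM-scaled CPM. Every fold change rests on 2 libraries against 2.

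A set of 30 gene lists was written before the data were examined, 21 of pathways and complexes and 9 of cell type markers. Of their 803 entries, 2 had no row in the table. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 30 lists. With an estimated correlation the test has only the few residual degrees of freedom of the 4 libraries. It has little power for any set of genes, so a miss decides nothing on its own. The count of members past the threshold is given over all genes tested and adjusted over the list alone. The self-contained test fry was run on the same lists.

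The rule for named genes was also fixed before the data were examined. It took Kif5c, then the 12 highest and the 8 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3 and both KIF5C libraries on the same side of both IgG libraries, leaving out predicted genes and pseudogenes. It also took up to 3 members with the smallest p-values from each list. Lrp1, Syn1, Rps28, Fosl2, Nr4a2 and Cox6a1, the small RNA classes, the rRNA-like loci and the abundant noncoding RNAs named below were chosen after their values were seen. Some genes that the rule took are not reported here.

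Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library totals without further scaling, no low-count filter, a mean count of at least 50, a replicate block, leaving out each library in turn, a minimum change of 2-fold, an adjusted p threshold of 0.1 and, for the relation with length, the median transcript of each gene and genes above the median of mean expression. With 1 library left out, the lone library of its group was assumed to vary like the other group. Chosen after the data were seen were a correction for GC content, a correction for GC content and transcript length (loess curves of span 0.3 for each library, entered as offsets in the edgeR fit), a fit of protein-coding genes alone and, for the relation with GC content, genes above the median of mean expression.

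The scripts were tested on simulated counts for the same 14357 genes, drawn from the means, spreads and library sizes of these libraries. In the simulated comparison of KIF5C with IgG, edgeR recovered 68% of 50 genes raised 2-fold, 62% of 50 lowered to 0.5-fold, 100% of those at 4-fold and at 0.25-fold, and called 0.135% of unchanged genes. The changed genes were drawn only from those with a mean count of at least 50, so recovery among less abundant genes was not measured. A list raised 1.5-fold was called, and 0 of the lists that shared no gene with it were. That raise was larger than the median shift of any list called in the real data. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often lists of correlated genes are called by mistake. The GC correction lowered a simulated correlation of fold change with GC content from 0.50 to 0.0072.

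Total counts per library ran from 11059266 to 15172432. Reads carried no molecular identifiers in the sources used here. The 1 binomial interval given is over genes, which are not independent, and it does not measure the spread between libraries. Replicate libraries differed by far more than sampling noise, with a chi-square of 215 per degree of freedom between the KIF5C libraries and 248 between the IgG libraries, so none was a second deposit of another.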

Results

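KIF5C is a neuronal kinesin heavy chain that moves cargo along microtubules, including particles that carry mRNA. The series asked which RNAs are associated with it in the mouse hippocampus. RNA from pooled co-immunoprecipitations was sequenced as 2 libraries with the KIF5C antibody (KIF5C libraries) and 2 with IgG (IgG libraries). The libraries held 12543510 counts (IgG control 1), 11059266 (IgG control 2), 15172432 (KIF5C 1) and 14623843 (KIF5C 2). Across the genes tested, log2 CPM correlated at 0.98 between the KIF5C libraries and at 0.97 between the IgG libraries, and libraries of different antibodies correlated at 0.95 to 0.97. The shares of 16S rRNA and of protein-coding genes differed more between replicate numbers than between antibodies. The mitochondrial 16S rRNA mt-Rnr2 took 7.36% of counts in IgG control 1 and 11.3% in KIF5C 1, but 32.2% in IgG control 2 and 31.9% in KIF5C 2. Protein-coding genes took 70.8% and 76.5% in the libraries numbered 1, and 39.2% and 49.9% in those numbered 2.

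RNAs of 478 genes were higher and RNAs of 107 genes were lower in the KIF5C precipitate than in the IgG precipitate. Among genes with a mean log2 CPM of at least 3, predicted genes left out, the highest was Ntng2 (chromosome 2, 29194541 to 29253005), which encodes the synaptic adhesion protein netrin-G2. It measured 14.5 and 29.0 CPM in the KIF5C libraries against 4.29 and 3.31 in the IgG libraries, a log2 fold change of 2.48 (SE 0.33, adjusted p = 0.00218). Next among these came Sart1, a splicing factor gene (chromosome 19, 5377523 to 5388703), at 2.20 (SE 0.23, adjusted p = 0.00029), and Chchd10, which encodes a protein of the mitochondrial intermembrane space (chromosome 10, 75933130 to 75937747), at 2.18 (SE 0.22, adjusted p = 0.00029). Pcsk1n, the gene of the prohormone convertase inhibitor proSAAS (chromosome X, 7919822 to 7924410), followed at 2.15 or 4.45-fold (SE 0.29, adjusted p = 0.00284).

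Other transcripts among the 12 highest at that abundance were Cep250, encoding a centrosomal linker protein (1.89), the ribosomal protein gene Rpl11 (1.86), the ubiquitin ligase adaptor gene Klhl12 (1.75), and the Nogo receptor family gene Rtn4rl2 (1.72). They also included the spermidine synthase gene Srm (1.72), the kinase gene Wnk2 (1.69), the clock repressor gene Nr1d1 (1.65) and Rnf31, encoding a linear ubiquitin ligase subunit (1.65). Their SEs lay between 0.23 and 0.37. All 12 stayed past the threshold in each of the 4 fits that left out 1 library. Rpl11 missed it with DESeq2 (adjusted p = 0.173), and its value was 1.15 without IgG replicate 1 and 2.95 without IgG replicate 2. Less abundant genes reached larger changes, up to 10.7-fold. Of the 478 genes higher in the KIF5C precipitate, 474 were protein-coding, and the median change was 2.10-fold.

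Among the lowest, Uqcrq, a subunit gene of respiratory complex III (chromosome 11, 53427922 to 53430831), fell from 81.9 and 71.6 CPM in the IgG libraries to 23.1 and 25.1, a log2 fold change of -1.67 (SE 0.22, adjusted p = 0.00218). The mitochondrial ribosomal protein gene Mrpl12 (-1.56, SE 0.25), the small Cajal body RNA Scarna6 (-1.45, SE 0.25) and Mpzl1, encoding a membrane glycoprotein (-1.42, SE 0.24), also fell. These 4 were the genes lower in the KIF5C precipitate that stayed past the threshold in every fit with 1 library left out. Ttr, the transthyretin gene, was lower at -1.38 (SE 0.29, adjusted p = 0.0166), with an adjusted p of 0.0813 without KIF5C replicate 2 and a value of -0.85 without IgG replicate 1. Nudt18, of the Nudix hydrolase family, was at -1.25 (SE 0.26). It missed the threshold without IgG replicate 2 (adjusted p = 0.0643), KIF5C replicate 1 (0.0938) or KIF5C replicate 2 (0.0805). The vault RNA Vaultrc5 was at -1.44 (SE 0.38), and at -0.79 (adjusted p = 0.32) without IgG replicate 2 and -0.87 (adjusted p = 0.292) without KIF5C replicate 1. It also missed the threshold with DESeq2 (adjusted p = 0.339). In the edgeR fit corrected for GC content and length, Ttr (-1.09, adjusted p = 0.0743) and Vaultrc5 (-0.98, adjusted p = 0.103) both missed the threshold. Lars2, the mitochondrial leucyl-tRNA synthetase gene, had the lowest value, -6.62 (SE 1.25), which rested on 2819 CPM in IgG control 2 against 20.5 in IgG control 1. Without that library it was -0.49 (adjusted p = 0.282), and with limma-voom its adjusted p was 0.0644.

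At an unadjusted p under 0.05 the counts were 1784 and 1301. Calls that went up made 81.7% of the total, against 64.9% (587 and 317 genes) after GC correction. With library totals the share was 20% (1 and 4 genes), and the median of all genes shifted by 0.14. The counts were 978 and 586 without IgG replicate 1, 275 and 39 without IgG replicate 2, 116 and 27 without KIF5C replicate 1, and 308 and 72 without KIF5C replicate 2. In all 4 of these fits, 79 of the 478 and 4 of the 107 stayed past the threshold.

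**Figure D1:**
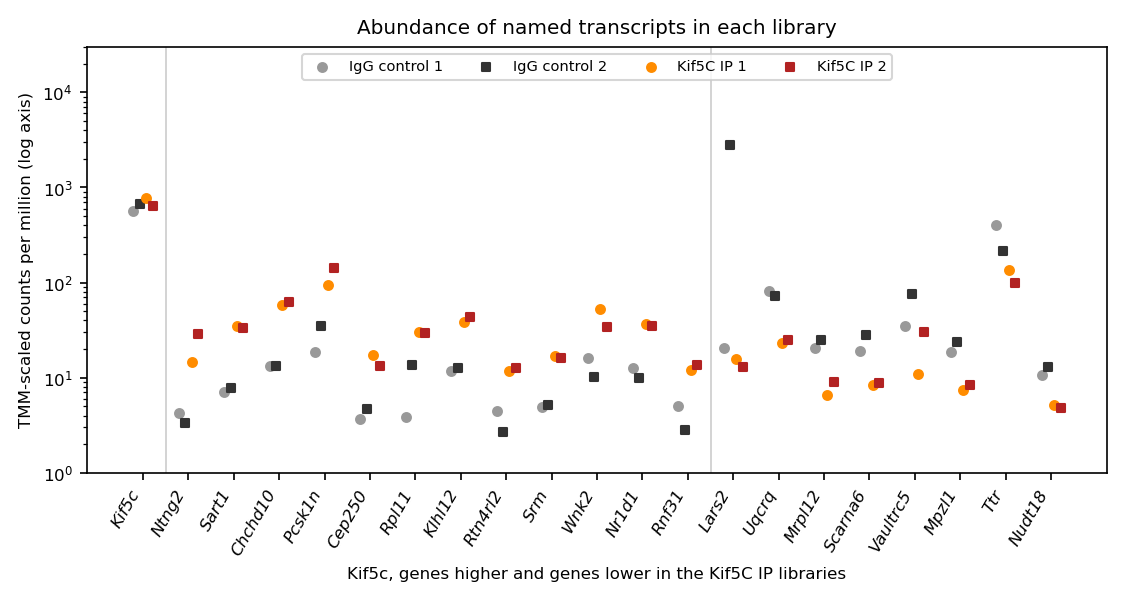
TMM-scaled CPM (log axis) of Kif5c, the 12 highest and the 8 lowest named transcripts, with 1 point per library (IgG control in grey and black, KIF5C in orange and red). Kif5c overlaps between antibodies, and Lars2 reaches 2819 in IgG control 2 while the other libraries lie between 13.1 and 20.5.

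The transcript of Kif5c itself (chromosome 2, 49619298 to 49774778) was present at 711 ± 101 CPM in the KIF5C libraries and 616 ± 71.6 in the IgG libraries (SD, n = 2 each). Its log2 fold change of 0.21 (SE 0.27, adjusted p = 0.702) was within the spread between libraries. In the edgeR fit none of the 7 tested kinesin-1 subunit genes passed over all genes or adjusted over the list alone (median 0.22, list adjusted p = 0.2). The list's median was 0.53 without IgG replicate 1 and 0.36 without KIF5C replicate 2. Kif5a had the smallest p of them, at 0.74 (SE 0.29, adjusted p = 0.152), and it passed with DESeq2 (adjusted p = 0.0214). Among 28 other kinesin and dynein genes, Kif21b was higher at 1.23 (SE 0.26, adjusted p = 0.0173) and 27 did not pass, with the same count adjusted over the list alone and 2 higher with DESeq2. Kif21b did not pass without IgG replicate 2 (adjusted p = 0.0653) or KIF5C replicate 1 (0.0578). The list had a median of 0.29 (adjusted p = 0.108), with 0.35 (0.0241) without KIF5C replicate 2 and 0.19 (0.521) without KIF5C replicate 1.

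Of the 30 gene lists, 5 lay above the other genes at the preset correlation, namely FMRP targets, presynaptic, postsynaptic and voltage-gated channel genes, and kinesin-1 cargo adaptors. None of the 5 was called with an estimated correlation (adjusted p = 0.716 for each). That test had little power here, so the miss does not decide whether correlation between genes makes the shifts. In the order named, the estimated correlations were 0.60, 0.11, 0.23, 0.57 and 0.10, each above the preset 0.01. The camera p-values at the preset correlation may therefore be too small. The test fry called none of the 5 (adjusted p from 0.239 to 0.348). Of 40 FMRP target transcripts, mRNAs bound by the fragile X protein, 36 had a positive fold change, and the median was 0.42 (camera adjusted p = 5.8e-06, adjusted p = 0.716 with an estimated correlation). App, the amyloid precursor gene, rose by 1.56 (SE 0.26), the ubiquitin ligase gene Ubr4 by 1.11 (SE 0.28), the lipoprotein receptor gene Lrp1 by 1.06 (SE 0.29) and the P/Q-type calcium channel gene Cacna1a by 0.98 (SE 0.22). None of the 40 fell and 36 did not pass, and 9 passed adjusted over the list alone. The list's median was 0.26 without KIF5C replicate 1 and 0.66 without KIF5C replicate 2. Of 39 presynaptic release and vesicle genes, 4 rose, 0 fell and 35 did not pass, and 14 passed adjusted over the list alone (median 0.28, camera adjusted p = 6.6e-05, adjusted p = 0.716 with an estimated correlation). Those that rose included the syntaxin gene Stx1a (1.36, SE 0.22), which acts in vesicle fusion, and the synapsin genes Syn3 (1.36, SE 0.29) and Syn1 (0.84, SE 0.23). The presynaptic median was 0.46 without KIF5C replicate 2.

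Of 33 postsynaptic density genes, the scaffold gene Dlgap4 (1.28, SE 0.22) and the catenin gene Ctnnd2 (0.85, SE 0.22) rose, 31 did not pass, and 5 passed adjusted over the list alone (median 0.42, camera adjusted p = 0.00121, adjusted p = 0.716 with an estimated correlation). Of 30 voltage-gated channel genes, 3 rose, among them Cacna1a and the sodium channel gene Scn8a (0.94, SE 0.24), 27 did not pass, and 7 passed adjusted over the list alone (median 0.28, camera adjusted p = 0.00146, adjusted p = 0.716 with an estimated correlation). The channel median was 0.45 without IgG replicate 1 and 0.48 without KIF5C replicate 2. Of 27 genes on the kinesin-1 cargo adaptor list, Jup (1.10, SE 0.24) and Mapk8ip3 (1.04, SE 0.26) rose and 25 did not pass. Adjusted over the list alone, 7 passed (median 0.35, camera adjusted p = 0.0122, adjusted p = 0.716 with an estimated correlation). Mapk8ip3 encodes JIP3, a scaffold that links cargo to kinesin-1. Jup encodes the junction protein plakoglobin and is counted because the list as written held it. Nothing here shows that plakoglobin is a kinesin-1 adaptor.

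These lists hold long transcripts, with a median of 11871 nt for FMRP targets, 8385 for channels, 6011 for postsynaptic, 4820 for presynaptic and 4365 for adaptor genes, against 3449 for all genes tested. After correction for GC content and length the presynaptic list stayed past the threshold (median 0.21, adjusted p = 0.00909). FMRP targets (0.17, adjusted p = 0.0626), channels (0.16, 0.0626), adaptors (0.12, 0.114) and postsynaptic genes (0.13, 0.247) did not. The adaptor list missed it without IgG replicate 2 (adjusted p = 0.0673), the channel list without IgG replicate 2 (0.058) or KIF5C replicate 1 (0.0798), and the postsynaptic list without KIF5C replicate 1 (0.0559). Of the 14 different members that rose, 14 passed without IgG replicate 1, 4 without IgG replicate 2, 4 without KIF5C replicate 1, 12 without KIF5C replicate 2 and 7 after correction for GC content and length. App, Stx1a and Dlgap4 passed in all 4 fits with 1 library left out. DESeq2 called 9 FMRP targets, 10 presynaptic, 6 postsynaptic, 3 channel and 6 adaptor genes, each higher.

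Cytosolic ribosomal protein mRNAs lay below the other genes, with a median of -0.40 over 77 genes (camera adjusted p = 1.0e-05, adjusted p = 0.716 with an estimated correlation). Of these, 11 fell, 3 rose and 63 did not pass. Adjusted over the list alone 29 fell and 4 rose, and with DESeq2 18 fell and 2 rose. Rps7 fell to -1.09 (SE 0.23), while those that rose included Rpl11 (1.86, SE 0.37) and Rps28 (1.12, SE 0.24). The list's median was negative in each of the 4 pairs of a KIF5C with an IgG library, from -0.23 to -0.58. Its members are short (median 1059 nt), and its median was -0.19 (adjusted p = 0.0626) after correction for GC content and length. Of the 14 members called, 14 passed without IgG replicate 1, 3 without IgG replicate 2, 2 without KIF5C replicate 1, 3 without KIF5C replicate 2 and 6 after correction for GC content and length. Of the members that rose, 2 passed in all 4 fits with 1 library left out, and 0 of those that fell did. Rpl11 was 1 of the 2, but it missed the threshold with DESeq2 (adjusted p = 0.173) and moved from 1.15 without IgG replicate 1 to 2.95 without IgG replicate 2.

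Nuclear-encoded respiratory chain genes went both ways. Of 76, 8 fell, 6 rose and 62 did not pass, and adjusted over the list alone 13 fell and 9 rose. Uqcrq was the lowest, while the complex I subunit genes Ndufb7 (1.54, SE 0.28) and Ndufs6 (1.27, SE 0.25) rose. The median was -0.20 (camera adjusted p = 0.036, adjusted p = 0.716 with an estimated correlation). The list missed the threshold without IgG replicate 1 (adjusted p = 0.135), IgG replicate 2 (0.0611) or KIF5C replicate 1 (0.323), and with library totals (0.164) or no low-count filter (0.0512), and its median was 0.0024 after correction for GC content and length, with a median length of 1186 nt. Of the 14 members called, 11 passed without IgG replicate 1, 10 without IgG replicate 2, 5 without KIF5C replicate 1 and 7 without KIF5C replicate 2. Uqcrq, Ndufb7, Ndufs6 and Cox6a1 passed in all 4 fits. None of 9 mitochondrially encoded genes passed, and 1 fell adjusted over the list alone (median -0.19, adjusted p = 0.545). Their median was positive against IgG control 1 (0.46 and 0.62) and negative against IgG control 2 (-0.76 and -0.47), and the list's adjusted p was 0.00197 without IgG replicate 1.

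**Figure D2:**
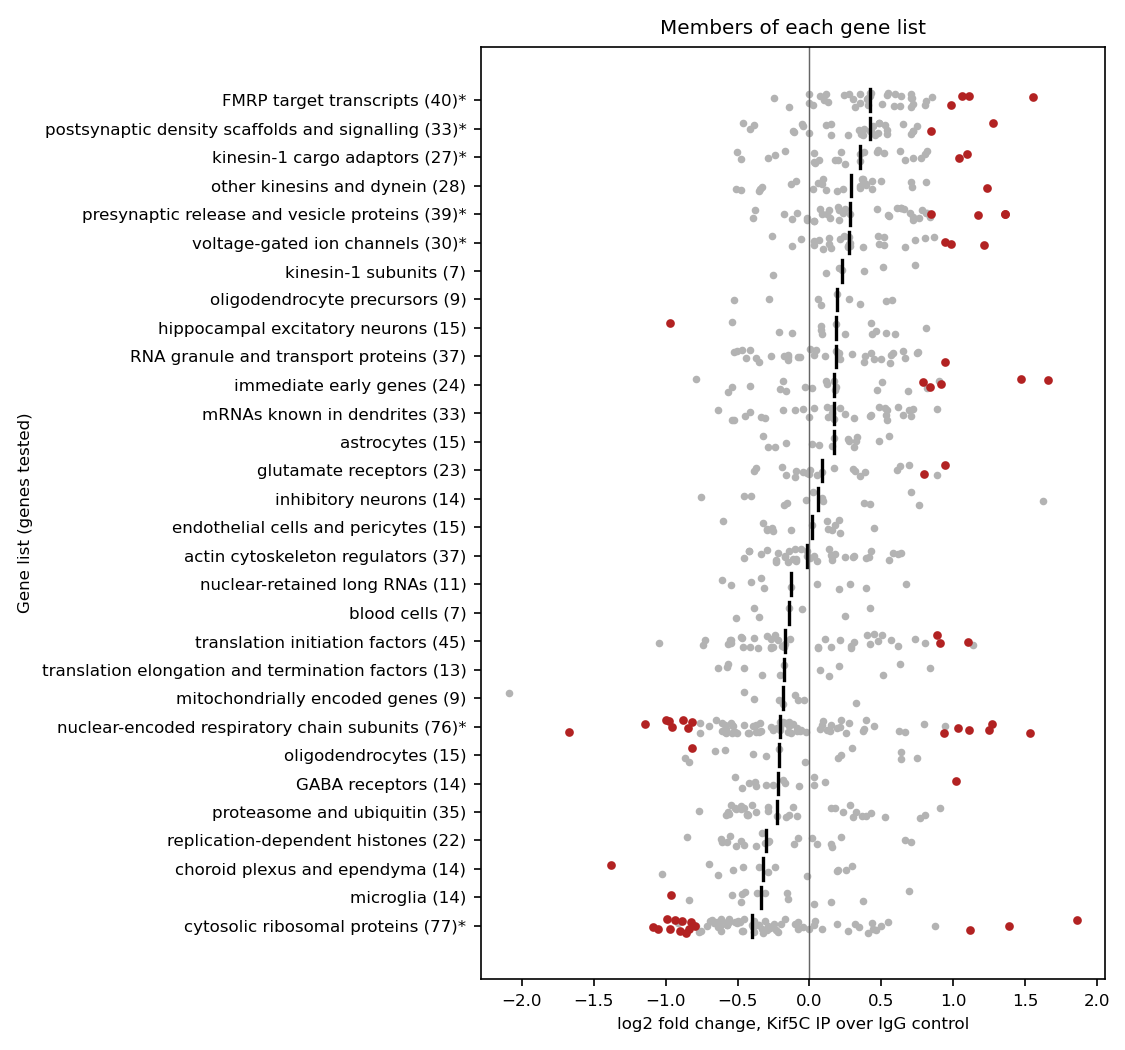
Log2 fold change (KIF5C over IgG) of every tested member of the 30 gene lists, 1 point per gene, red where its adjusted p was under 0.05, with a bar at the list's median. An asterisk marks a camera adjusted p under 0.05 at the preset correlation, and medians run from -0.40 for ribosomal protein genes to 0.42 for FMRP targets.

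Immediate early genes, genes induced by neuronal activity, included 5 of 24 that rose, with 19 that did not pass and, adjusted over the list alone, 6 higher and 1 lower. Egr4 (1.66, SE 0.29), Egr3 (1.47, SE 0.24) and Egr1 (0.92, SE 0.21) belong to 1 family of zinc finger transcription factors, and Nr4a2 (0.84, SE 0.21) and Fosl2 (0.79, SE 0.21) were the others. As a list, with a median GC content of 54.3%, they were not called (median 0.17, adjusted p = 0.0681), and their adjusted p was 0.0327 without IgG replicate 2, 0.0337 without KIF5C replicate 1 and 0.0289 with DESeq2, against 0.355 without IgG replicate 1 and 0.186 without KIF5C replicate 2. Among 45 translation initiation factors, Eif3g (1.11, SE 0.23), Eif4g3 (0.91, SE 0.22) and Eif3f (0.89, SE 0.23) rose, 42 did not pass, and 4 rose and 3 fell adjusted over the list alone. Their median (-0.17) and mean (0.02) differed in sign, and the list was not called (adjusted p = 0.848). The median turned to 0.08 without IgG replicate 2, and DESeq2 called 3 higher and 2 lower. Hnrnpab, an RNA-binding protein gene, was the 1 of 37 RNA granule genes that rose (0.94, SE 0.24), with 3 adjusted over the list alone and 2 with DESeq2 (median 0.18, adjusted p = 0.215). That list's adjusted p was 0.0154 without IgG replicate 2 and 0.00809 after GC correction, but its median was 0.02 (adjusted p = 0.927) without IgG replicate 1 and -0.07 for KIF5C 2 over IgG control 2.

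Gabbr2 (1.02, SE 0.24) was the 1 of 14 GABA receptor genes that rose, over all genes and adjusted over the list alone (median -0.22, adjusted p = 0.225). Grm2 (0.94, SE 0.23) and Grik3 (0.80, SE 0.22) were the 2 of 23 glutamate receptor genes that rose, and 3 did so adjusted over the list alone and 4 with DESeq2 (median 0.08, adjusted p = 0.152, with medians of 0.15 to 0.21 when 1 library was left out). None of 33 mRNAs known in dendrites passed in the edgeR fit, also adjusted over the list alone, while DESeq2 called 5 higher and 1 lower (median 0.17, adjusted p = 0.132, and 0.41 as the median without IgG replicate 1). In the edgeR fit no member passed among 13 elongation and termination factors (median -0.18, adjusted p = 0.698), 37 actin regulators (median -0.02, mean 0.04, adjusted p = 0.698), 35 proteasome and ubiquitin genes (median -0.22, adjusted p = 0.264), 11 nuclear-retained long RNAs (median -0.13, adjusted p = 0.698) and 22 histone genes (median -0.30, adjusted p = 0.112). The histone list passed without KIF5C replicate 2 (median -0.69, adjusted p = 2.4e-05), after GC correction (0.0196), with limma-voom (0.0307) and at a mean count of at least 50 (0.0141). Its median turned to 0.03 (adjusted p = 0.66) without KIF5C replicate 1 and was -0.08 (0.715) after correction for GC content and length. Adjusted over the list alone, 2 proteasome and ubiquitin genes rose, 1 fell, and 0 members of the other 4 lists passed. DESeq2 called 1 elongation and termination factor higher (Eef2, 0.84, adjusted p = 0.00568) and 1 lower, 1 actin regulator higher (Cfl1, 0.64, 0.0452), 2 proteasome and ubiquitin genes higher (Psmd2, 0.80, 0.0144, and Psmb7, 0.77, 0.0316) and 1 lower (Psmb3, -0.77, 0.0443), and 1 histone gene lower (Hist1h4h, -0.85, 0.0315). The elongation and termination median turned to 0.01 without IgG replicate 2, that of actin regulators to 0.10 without it, and that of nuclear-retained RNAs to 0.12 without KIF5C replicate 2. Of the 23 lists not called, cell type markers included, the medians of 10 turned sign and those of 20 moved by over 1.5 times when 1 of the libraries was left out. Of the 17 members called in lists that were not called, cell type markers included, 15 passed without IgG replicate 1, 6 without IgG replicate 2, 3 without KIF5C replicate 1, 7 without KIF5C replicate 2 and 8 after correction for GC content and length. Egr3 and Egr4 passed in all 4 fits with 1 library left out.

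Cell type markers were compared in the same way, since RNA from any cell of the tissue can enter a precipitate. No marker list was called in the edgeR fit of the 4 libraries without correction. The medians were 0.19 for hippocampal excitatory neurons (adjusted p = 0.305), 0.06 for inhibitory neurons (0.447), 0.17 for astrocytes (0.411), -0.21 for oligodendrocytes (0.445) and 0.19 for their precursors (0.447). They were -0.34 for microglia (0.0983), -0.32 for choroid plexus and ependyma (0.112), 0.02 for endothelial cells and pericytes with a mean of -0.05 (0.704), and -0.14 for blood cells (0.698). The microglia list passed after GC correction (adjusted p = 0.0238), at a mean count of at least 50 (0.0286) and without IgG replicate 2 (0.0307), and the choroid plexus list without KIF5C replicate 2 (0.0341). The microglia median was -0.17 (0.409) without IgG replicate 1, and that of the choroid plexus -0.04 (0.387) without KIF5C replicate 1. That of astrocytes ran from -0.002 without IgG replicate 2 to 0.35 without KIF5C replicate 2, that of inhibitory neurons turned to -0.06 without KIF5C replicate 1, and that of precursors was 0.42 and that of excitatory neurons 0.33 without IgG replicate 1. The endothelial median turned to -0.10 without IgG replicate 2 and that of blood cells to 0.07 without IgG replicate 1. Single markers fell in 4 lists, namely Spink8 of excitatory neurons (-0.97, SE 0.23), the myelin gene Mog (-0.82, SE 0.21), the microglial gene Tyrobp (-0.96, SE 0.24) and Ttr of the choroid plexus. No marker rose over all genes tested in the edgeR fit, and DESeq2 called 1 of excitatory neurons higher (Wfs1, 0.81, adjusted p = 0.0277). Adjusted over the list alone, 1 marker of excitatory neurons rose and 1 fell, 3 of inhibitory neurons rose and 1 fell, 3 of oligodendrocytes rose and 5 fell, 2 of microglia fell and 1 of choroid plexus fell.

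Genes higher in the KIF5C precipitate had a median GC content of 55.5%, against 50.6% for those lower and 49.7% for all genes tested. Their median transcript length was 3986 nt, against 1311 nt for those lower. Across genes, which are not independent replicates, log2 fold change correlated with GC content at a Spearman rho of 0.33 and with length at 0.20. With no low-count filter these were 0.194 and 0.105, and with the median transcript of each gene the rho for length was 0.116. For GC content the 4 pairs of single libraries gave 0.084 (KIF5C 1 over IgG control 1), 0.179 (KIF5C 2 over IgG control 1), 0.373 (KIF5C 1 over IgG control 2) and 0.487 (KIF5C 2 over IgG control 2). Without IgG replicate 2 the rho was 0.136. For length the pairs with KIF5C 1 gave 0.275 and 0.253, and those with KIF5C 2 gave 0.049 and 0.079. Without KIF5C replicate 1 the rho for length was 0.091. Libraries of 1 antibody also differed this way, with a rho for GC content of 0.41 for IgG control 1 over IgG control 2 and a rho for length of 0.336 for KIF5C 1 over KIF5C 2.

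**Figure D3:**
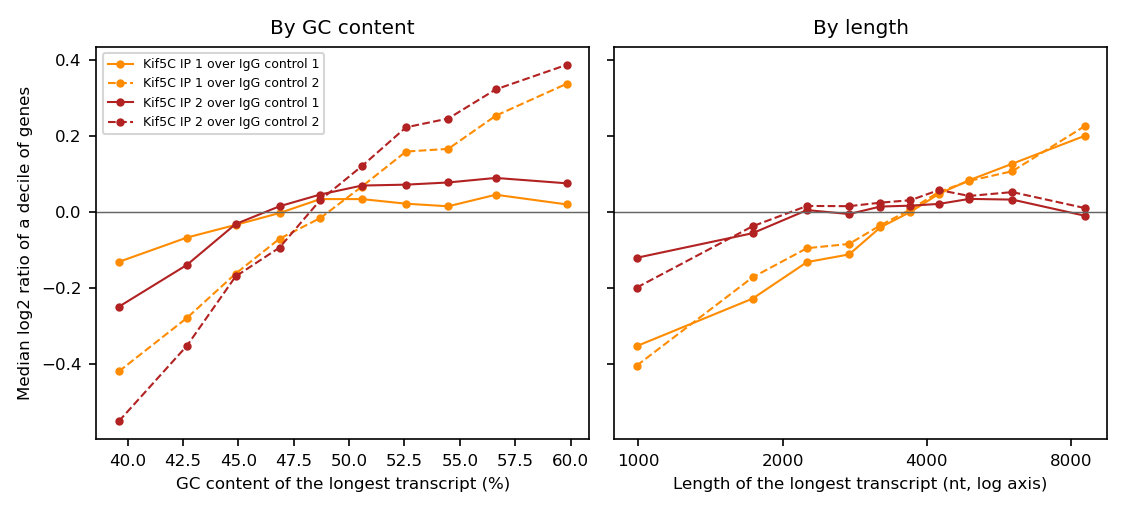
Median log2 ratio of a KIF5C library over an IgG library for genes in 10 equal groups by GC content (left) and by transcript length (right, log axis), with 1 line per pair of libraries. Pairs with IgG control 2 (dashed) rise from -0.55 and -0.42 to 0.39 and 0.34 with GC content, and pairs with KIF5C 1 (orange) rise with length.

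The authors' deposited table lists 759 genes with an adjusted p under 0.05, of which 640 were higher and 119 lower in the KIF5C precipitate. Its deposited log2 fold changes, turned here into folds of KIF5C over IgG, give 3.84 for Chchd10 and 0.358 for Uqcrq. In the same way Eif3g has a fold of 1.95 (authors' adjusted p 0.00224) and Kif5a a fold of 1.61 (0.0134), while Kif5c has 1.15 (0.591). Of its 758 calls whose gene name could be read, 100% had the same direction in the edgeR fit (exact 95% binomial interval 99.5% to 100%), and 445 higher and 72 lower genes were called in both. Kif5a was called there and with DESeq2 here (adjusted p = 0.0214), but not in the edgeR fit. Both used the same counts, so the match is no second measurement.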

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

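The corrections for GC content and length and the fit of protein-coding genes were chosen after the data were seen. Direction was kept by the 478 and 107 called genes, where tested, in each alternative except 2 genes without IgG control replicate 2. This was largely fixed beforehand and is no test of the calls. For all 478 higher and 105 of the 107 lower genes, both KIF5C libraries already lay on the same side of both IgG libraries. Genes higher and lower in the KIF5C precipitate numbered 1 and 4 with library totals, 902 and 261 with no low-count filter (more genes tested), 302 and 51 at a minimum change of 2-fold, and 889 and 342 at an adjusted p threshold of 0.1. There were 317 lower genes after GC correction and 164 among protein-coding genes only, and leaving out 1 library gave 116 to 978 and 27 to 586. With a replicate block the counts were 1162 and 517 (69.2% higher) and included all 478 and 107, and Kif5a passed there (adjusted p = 0.0333), while the respiratory chain list did not (0.0915). The numbers are not stated to pair the libraries, and same-numbered libraries deviated together at a correlation of 0.14. The 5 and 2 gene lists became 0 and 0 with an estimated correlation and with fry, and 1 and 0 after correction for GC content and length. The test with an estimated correlation had little power with so few libraries. Lower lists numbered 1 with library totals, with no low-count filter or with the block, 4 after GC correction or at a mean count of at least 50, and 1 to 4 without 1 library. Higher lists numbered 4 to 6 without 1 library. The rho with GC content became 0.0084 after GC correction, 0.091 after GC and length correction, and 0.136 to 0.429 without 1 library. That with length reversed to -0.0017, and the respiratory chain median to 0.0024, after GC and length correction, which removes such trends by construction. Kif5c stayed between 0.05 and 0.41 and was never past the threshold, and all calls of the authors' table kept their direction. The cause of the other changes was not tested. At the depth and spread of these libraries 68% of simulated 2-fold increases were recovered among genes with a mean count of at least 50. Whether depth or spread limits small changes was not tested.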

Other observations

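Of 12 RNA classes, tested after the data were seen, 8 noncoding classes, small and long, lay below the other genes in the KIF5C precipitate at the preset correlation, and none was called with an estimated correlation. Protein-coding genes were called higher (camera adjusted p = 0.000119, adjusted p = 0.111 with an estimated correlation), though their median was -0.01. Among the small RNAs, 79 snoRNAs had a median log2 fold change of -0.77 (camera adjusted p = 1.8e-12, adjusted p = 0.52 with an estimated correlation), with 5 lower and 0 higher. Of 11 scaRNAs, guides for modification of spliceosomal RNA, 4 were lower and 0 higher, with a median of -1.09 (camera adjusted p = 0.00044, adjusted p = 0.346 with an estimated correlation). The scaRNA median lay between -0.89 and -1.16 in each of the 4 pairs of a KIF5C with an IgG library, was -0.65 without IgG control replicate 1 and was -0.61 after correction for GC content and length. The snoRNA median was -0.45 without IgG control replicate 2 and -0.12 after that correction. The 21 genes annotated as miscellaneous RNA had a median of -0.90 (camera adjusted p = 2.9e-06, adjusted p = 0.52 with an estimated correlation), with 2 lower and 0 higher. Their median was -0.42 without IgG control replicate 2, -0.45 without KIF5C replicate 1 and -0.43 after that correction. For 16 snRNAs the median was also -0.90 (camera adjusted p = 0.0132, adjusted p = 0.653 with an estimated correlation) with 0 genes past the threshold, but it was 0.56 without IgG control replicate 2, -0.16 without KIF5C replicate 1, -1.65 without IgG control replicate 1 and -2.21 without KIF5C replicate 2, and the pairs ran from -3.00 to 1.22. The 15 miRNA genes were not called (median -0.15, camera adjusted p = 0.859), with 1 lower and 0 higher, and their median was 0.62 after correction for GC content and length. The long classes had medians of -0.30 for 215 antisense genes (camera adjusted p = 0.000441), -0.16 for 240 lincRNAs (0.00362), -0.19 for 152 processed transcripts (0.0157) and -0.27 for 35 lncRNAs at bidirectional promoters (0.0184). With an estimated correlation the adjusted p was 0.52, 0.52, 0.551 and 0.653. Without IgG control replicate 2 they were -0.24, -0.11, -0.07 and -0.12, and without KIF5C replicate 1 they were -0.16, -0.14, -0.09 and -0.14. Without IgG control replicate 1 they were -0.29, -0.28, -0.29 and -0.53, and without KIF5C replicate 2 they were -0.38, -0.26, -0.19 and -0.37. After correction for GC content and length they were -0.13, -0.06, -0.02 and -0.19, and the snRNA median was -0.17. Rn7sk, the 7SK RNA, took 12.1% and 16.0% of counts in the IgG libraries and 5.44% and 11.4% in the KIF5C libraries. Rpph1, the RNase P RNA, took 3.47% and 4.56% against 1.28% and 3.35%. These are shares of all counts without TMM scaling, and no test of either RNA is given here. The TMM factors were 1.25 and 0.71 for the IgG libraries and 1.28 and 0.88 for the KIF5C libraries. Scaled by them, KIF5C 2 lay above IgG control 1 for both RNAs.

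Of 91 families of genes with a shared symbol stem, also chosen after the data were seen, 6 were called at the preset correlation, each lower, and none was with an estimated correlation (adjusted p = 0.947 for each of the 6). The 19 Snora genes, H/ACA snoRNAs, had a median of -0.88 (camera adjusted p = 5.6e-05) with 1 lower and 0 higher. The 22 Nudt genes had a median of -0.49 (0.00389), with 1 lower and 1 higher, and 331 Zfp genes of zinc finger proteins had -0.25 (0.0123), with 5 lower and 9 higher. The 47 Mrpl genes of the large mitochondrial ribosomal subunit had -0.33 (0.0169), with 2 lower and 0 higher. The stems Rpl (-0.36, 0.00389) and Rps (-0.35, 0.0169) overlap the ribosomal protein list. Among other translation families, 29 Mrps genes (-0.15, 0.138) and 52 Eif genes (-0.16, 0.918) were not called. After correction for GC content and length the medians were -0.31 for Snora, -0.46 for Nudt, -0.18 for Zfp, -0.20 for Mrpl, -0.16 for Rpl and -0.21 for Rps. Without IgG control replicate 2 they were -0.47 for Snora, -0.12 for Zfp and -0.23 for Rpl, each smaller by over 1.5 times.

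The tests of explanations in the paragraphs that follow were all chosen after the results were seen. GC-rich transcripts were higher in the KIF5C precipitate. A GC bias between the 2 IgG libraries may make the larger part of that trend. The rho fell from 0.33 to 0.136 without IgG control replicate 2, and IgG control 1 over IgG control 2 gave 0.41 with no difference in antibody. The fall follows from the pairs, which gave 0.373 and 0.487 with IgG control 2 against 0.084 and 0.179 with IgG control 1. These values cannot tell which IgG library is biased. The remaining trend stays open, as a library effect or as a property of the RNAs that associate with KIF5C. GC correction removes only the average trend, so it cannot decide on GC effects that vary from gene to gene. That trend was small, with a median log2 fold change of 0.18 in the most GC-rich of 10 equal groups of genes. The higher calls had a median change of 2.10-fold. The average GC trend as the whole cause of the higher calls is argued against, because 91.2% of the 478 higher genes stayed past the threshold after GC correction. Fewer stayed after correction for both GC content and length, namely 311 of the 478 higher and 43 of the 107 lower genes. An association of the remaining transcripts with KIF5C is the biological explanation the design gives, and with no input RNA analysed here it was not tested further.

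Ribosomal protein mRNAs were lower in the KIF5C precipitate. IgG control replicate 2 alone is argued against, since the list's median was -0.33 without it against -0.40 with it. Short length and expression level may account for most of the shift. Lists matched on both had a median of -0.27 (95% of them from -0.39 to -0.14), and 133 of 10000 were as low as the real list. Whether they account for all of it cannot be told apart from a further depletion. Ribosomal protein genes vary together between libraries (estimated correlation 0.47), and the drawn lists were not matched on this. How far members of the matched lists vary together is not given here. A lower share of these mRNAs on KIF5C stays open.

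A set of 4 loci, Lars2, Gm15564, Gm24187 and Gm42418, was far higher in IgG control 2 than in IgG control 1, by 138-fold, 254-fold, 189-fold and 32.6-fold. Their log2 fold changes were -6.62, -6.52, -5.36 and -4.74 with 4 libraries. Without IgG control replicate 2 they were -0.49, 0.45, 1.17 and -0.66. Gm42418 (chromosome 17, 39846958 to 39848788) shares 1245 bases with the locus that RefSeq gives for Rn18s-rs5, an 18S rRNA gene, and Lars2 shares 22 sequences of 31 bases with Gm15564. A candidate source is carry-over of 18S rRNA. Rn18s-rs5 was itself called lower in the edgeR fit (-2.45, SE 0.63, adjusted p = 0.0381), and was at -0.99 without IgG control replicate 2. Between the IgG libraries Rn18s-rs5 differed 4.46-fold, and the smallest rise of the 4 loci was 7.31 times that. This cannot decide the question, because the loci were chosen for their rise. Reads of Gm42418 and Rn18s-rs5 can also be shared between them. Carry-over of 18S rRNA or of another part of the rRNA precursor stays open, and no biological explanation was tested.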
